A study of Carya illinoinensis and Pinus armandii with 24 samples.

How the data were processed

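RNA was measured in leaves of seedlings of 2 tree species, pecan (Carya illinoinensis) and Armand pine (Pinus armandii), 30 months after inoculation. Per the labels, the seedlings of each species had received the truffle Tuber indicum, the truffle T. panzhihuanense or no inoculum, with 4 biological replicates in each of the 3 groups and 24 libraries in all. The labels do not say whether each replicate was a separate seedling or a pool, so the p-values measure the spread between these libraries only. Per the labels' protocols, total RNA was extracted with TRIzol and libraries were made with the VAHTS Universal V6 kit. Trimmomatic, a read trimmer, is listed without a version in the submitters' processing notes; the aligner, the abundance estimator and their settings are not given in the sources used here.

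The authors deposited FPKM values (fragment counts scaled by contig length and by the mapped fragments of the library) in a separate table for each species, with 38049 contigs for Carya and 32009 for Pinus. The contig IDs carry the names that the de novo assembler Trinity gives, followed by a number from 1 to 4 whose meaning is not stated. Each library was matched to its column by the library name in its label. The files do not pair the contigs with gene names or descriptions. A reference gene table of the pecan assembly C.illinoinensisPawnee_v1 was searched for the IDs, and 0 of them matched in either species. For this reason the 30 gene lists that had been fixed by description (photosynthesis, nutrient transport, defence, hormones, cell types and others) could not be tested, and 0 lists were run. Contigs are therefore named by ID alone.

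FPKM values hold no counts, and the absolute sequencing depth is unknown. The low values were not whole multiples of a single step, since they reached 8.46e-123 in Carya, so whole fragments could not be recovered. Relative depth was estimated from contigs with values between 0.02 and 0.6 FPKM in a pair of libraries, whose ratios pile up where both libraries hold the same small number of fragments. Relative to the mean library of the species, it ran from 0.960 to 1.07 in Carya and from 0.974 to 1.05 in Pinus. Only ratios in a window around 1 were searched, so a large difference in depth could not have been found. An exact 0 can be a failed estimate, so such a contig is said to be listed at 0, and no fold is given against a group that is listed at 0 throughout. Of all values, 3.51% were 0 in Carya and 4.58% in Pinus. No pair of libraries held identical values (0 pairs).

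For the tests, contigs with at least 1 FPKM in at least 4 of the 12 libraries of a species were kept, which left 33720 in Carya and 26599 in Pinus. Values were transformed to log2(FPKM + 1), so a log2 fold change understates the change of low contigs. Group means were fitted with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with a mean trend) over the 12 libraries of a species. Contigs were called at a 2-sided Benjamini-Hochberg adjusted p under 0.05, separately for each of the 3 comparisons per species. The species were never fitted together. Since no table pairs the IDs with descriptions, the contigs named for each comparison were, by the rule set for that case, the 2 with the largest log2 fold change in each direction among called contigs whose 4 libraries did not overlap between the groups and whose higher group averaged at least 5 FPKM. The rule, the tests, the filter and most alternatives were fixed before the data were examined.

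The procedure was tested on simulated data built from the real contig means and spreads, with 200 contigs changed. Over the 3 comparisons, changes of 1 on the log2 scale were recovered for 59%, 62% and 65% of those contigs among 33720 in Carya and for 77%, 72% and 77% among 26599 in Pinus. Changes of 0.5 were recovered for 30%, 27% and 27% in Carya and for 32%, 35% and 34% in Pinus. Between 4 and 8 unchanged contigs were called per run. The simulated noise was independent between contigs, and far more contigs were called in the real data. These rates and counts therefore do not carry over to the real fits.

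Library profiles were described by the median contig, the share of all FPKM in the 100 most abundant contigs, and the effective number of contigs (the exponential of the Shannon entropy of the FPKM shares, which grows as the shares become more even). Their groups were compared with 2-sided exact permutation tests, whose smallest p is 0.0286 for 4 libraries against 4, with Benjamini-Hochberg adjustment over 42 comparisons. These measures and tests were chosen after the data had been seen. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used. Alternatives covered the pseudocount (0.1), the filter, the scaling of the libraries (a common total, quantile normalization, centring on the median log2 ratio), the libraries in the fit, a replicate block, array weights, a fold threshold, and leaving out each library in turn. Quantile normalization and centring remove a shift common to most contigs by construction, so the share of higher calls after them is no test of whether such a shift exists. Because both inoculated groups were compared with the same controls, the overlap of their calls was set beside that of independent lists and of fits with the controls split, and the correlation and covariance of their fold changes beside 100 simulations of unchanged groups.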

Results

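Leaf transcriptomes were profiled in 2 ectomycorrhizal host trees, the broadleaf pecan and the conifer Armand pine, to ask how inoculation with each of 2 truffles relates to expression in the leaf. T. indicum is a black truffle and T. panzhihuanense a white truffle, and both form ectomycorrhizas on tree roots. Each species had 4 control, 4 T. indicum and 4 T. panzhihuanense libraries, all sampled 30 months after inoculation. Total FPKM per library ran from 703896 to 773812 in Carya and from 812559 to 877243 in Pinus. The absolute depth is unknown. Estimated relative depths ran from 0.960 to 1.07 in Carya and from 0.974 to 1.05 in Pinus, though the estimate could not find large differences. Carya T. panzhihuanense libraries had 1.05 times the relative depth of controls without overlap (exact permutation p = 0.0286, adjusted p = 0.0857).

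Leaves of each group were more alike than leaves of different groups in both species. The Spearman correlation between Carya libraries, taken across contigs, averaged 0.937 within groups (range 0.920 to 0.951) and 0.866 between groups (0.844 to 0.885). For Pinus it averaged 0.949 within groups (0.940 to 0.955) and 0.888 between them (0.860 to 0.907). The first principal component took 40.7% of the variance in Carya and separated the 3 groups, and the second took 29.5% and set T. panzhihuanense leaves apart from both others. In Pinus the first (40.8%) set T. panzhihuanense leaves apart and the second (29.9%) separated T. indicum from control leaves.

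**Figure D1:**
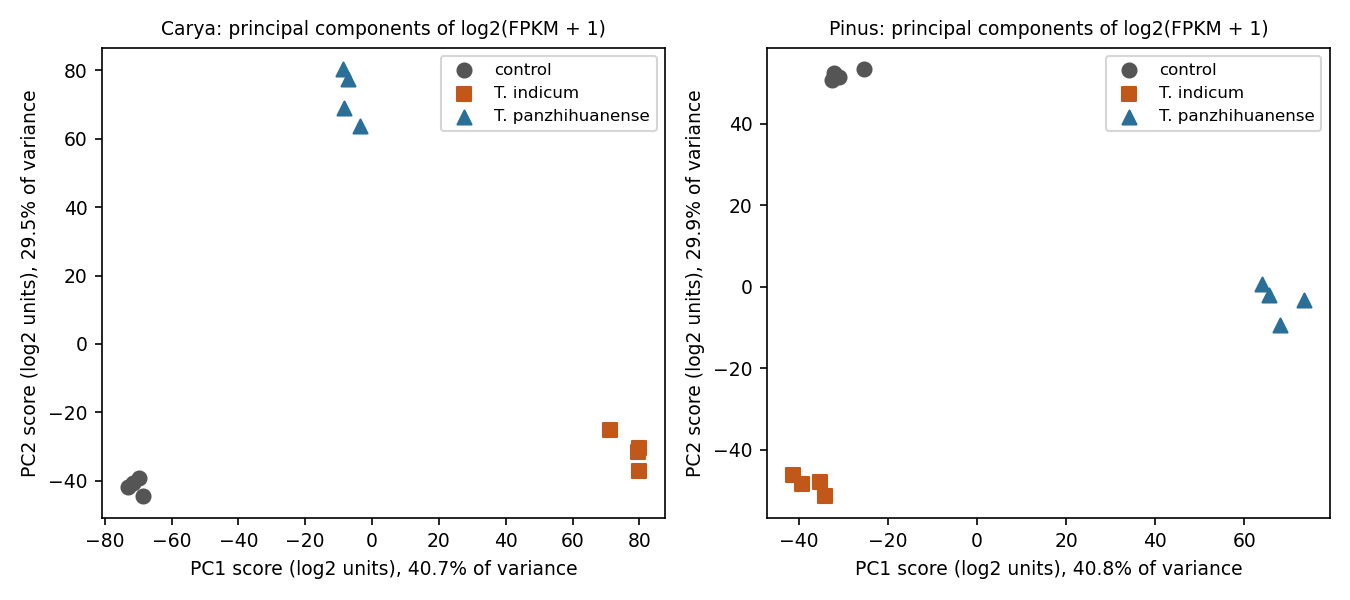
Scores of the 12 libraries of each species on the first 2 principal components of log2(FPKM + 1), in log2 units, with 1 point per library and colour and shape giving the group. The 4 libraries of each group sit together, and the first component takes 40.7% of the variance in Carya and 40.8% in Pinus.

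Carya leaves from T. indicum seedlings had a more even transcript profile than control leaves. Their effective number of contigs was 8774 ± 611 against 6854 ± 257 in controls (SD, n = 4 each), a ratio of 1.28, and their 100 most abundant contigs held 13.6% ± 0.821 of all FPKM against 15.8% ± 0.364. Their median contig stood at 4.03 ± 0.423 FPKM against 2.99 ± 0.106. Carya leaves with T. panzhihuanense moved the other way in the share of the 100 most abundant contigs, which was 18.4% ± 1.01. Part of this rise came from 6 contigs that were low in all controls and in T. indicum replicate 1, since without them the share was 17.3% ± 0.810 against 15.8% ± 0.364 (SD, n = 4 each). In Pinus, both inoculated groups had more even profiles than controls, with 4390 ± 322 effective contigs for T. indicum and 4182 ± 317 for T. panzhihuanense against 3664 ± 62.7 (SD, n = 4 each). The 4 libraries of the groups did not overlap in any of these differences, each with an exact permutation p of 0.0286, the smallest that 4 against 4 can give. After adjustment over 42 comparisons the value was 0.0857, so none passed 0.05. The effective numbers of Pinus T. panzhihuanense and control nearly met, at 3751.23 in T. panzhihuanense replicate 1 and 3750.76 in control replicate 3.

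**Figure D2:**
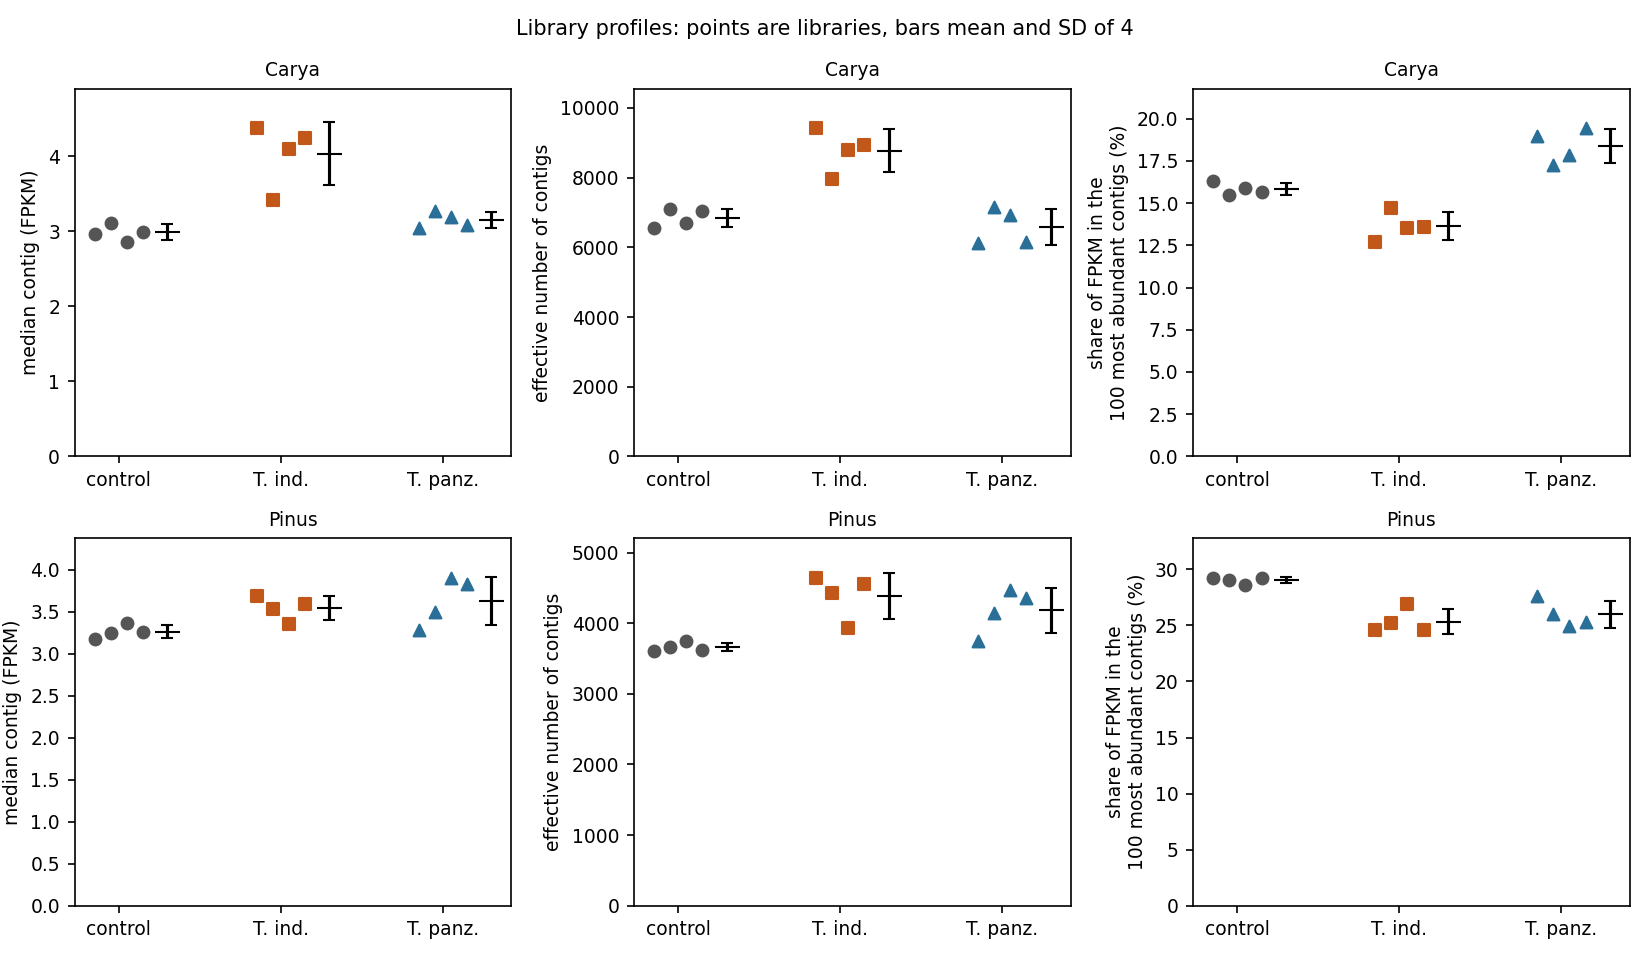
Median contig in FPKM, effective number of contigs and percent of FPKM in the 100 most abundant contigs, for each library (points), with the mean and SD of the 4 libraries of a group (bars), Carya above and Pinus below. The Carya T. indicum libraries lie above controls in effective number (8774 against 6854 on average) and below them in the share of the most abundant contigs.

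The first comparison asked which transcripts of the pecan leaf differed between T. indicum and control seedlings. Of the contigs tested, 58.5% did, and most of these were higher with the truffle in the values as deposited. TRINITY_DN1858_c0_g1_i1_3 rose from 15.8 ± 1.81 FPKM in controls to 482 ± 21.3 with T. indicum (SD, n = 4 each), a log2 fold change of 4.85 ± 0.10 (SE; adjusted p = 1.02e-11). TRINITY_DN16005_c0_g2_i1_4 rose from 27.2 ± 4.76 to 2906 ± 2059 FPKM, by 5.39 ± 1.21 on the log2 scale (adjusted p = 0.00198). Its T. indicum libraries were spread widely, since replicate 1 stood at 33.5 FPKM, just above the highest control at 33.2, and the log2 fold change was 7.08 without that replicate and 4.71, 4.95 and 4.82 without replicates 2, 3 and 4. TRINITY_DN19002_c0_g2_i1_1 fell by 4.30 on the log2 scale, from 40.6 ± 9.14 to 1.07 ± 0.232 FPKM (adjusted p = 4.18e-10). TRINITY_DN18620_c2_g1_i1_4 fell by 4.28, from 21.5 ± 1.68 FPKM to between 6.09e-15 and 0.466 FPKM in the T. indicum libraries (adjusted p = 1.11e-09). In total, limma called 19740 of 33720 contigs, 14688 higher and 5052 lower with T. indicum, of which 4386 and 2034 changed by at least 1 on the log2 scale. The libraries of both groups did not overlap for 55.0% of contigs, where chance gives 2.86%. The median over all tested contigs lay 0.33 above control on the log2 scale, and the direction of many calls depended on it: 74.4% of the calls were higher as deposited, 72.7% after rescaling to a common total, 54.2% after quantile normalization and 48.4% after centring each library on its median ratio. By the number that ends the contig ID, whose meaning is not stated, the share as deposited ran from 62.0% (number 2) to 87.5% (number 3). Relative to the centred libraries, the 4 named contigs changed by 4.52, 5.06, -4.63 and -4.61 in the order given.

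Set against the same controls, Carya leaves with T. panzhihuanense held abundant contigs that were low or listed at 0 in control leaves. TRINITY_DN18801_c1_g2_i3_1 rose from 6.36 ± 1.53 FPKM in controls to 3628 ± 1203 with T. panzhihuanense (SD, n = 4 each), by 8.91 ± 1.46 on the log2 scale (SE; adjusted p = 0.000266). TRINITY_DN19041_c0_g2_i1_3 was listed at 0 in all 4 controls and stood between 1805 and 3498 FPKM in the T. panzhihuanense libraries (adjusted p = 0.000414). Both contigs were also high in T. indicum replicates 2, 3 and 4 and low or listed at 0 in T. indicum replicate 1. The fit pools the spread over all 12 libraries, so the SE and adjusted p given here include that split of the T. indicum group. With limma on only the 8 T. panzhihuanense and control libraries, the adjusted p was 1.39e-08 and 2.59e-09 in the order given. Both contigs and TRINITY_DN16005_c0_g2_i1_4 belong to 6 contigs that switched together inside the T. indicum group. The source of these contigs is open, so they may not be separate changes of the leaf. TRINITY_DN18838_c0_g1_i1_2 fell by 5.92, from 77.1 ± 3.67 to 0.287 ± 0.0831 FPKM (adjusted p = 2.91e-13). TRINITY_DN10762_c0_g1_i1_1 fell by 4.97, from 70.7 ± 11.2 to 1.52 ± 1.38 FPKM (adjusted p = 2.97e-08). limma called 15149 contigs (44.9%), 8022 higher and 7127 lower, of which 2195 and 2166 changed by at least 1 on the log2 scale. The share of higher calls was 53.0% as deposited and 49.5% after centring, and the median over all contigs lay 0.04 above control. This balance combined opposite directions, with 65.2% of calls higher for contigs whose ID ends in 3 and 34.2% for those ending in 4.

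The comparison of the inoculated groups asked whether the leaf profile differed with the truffle species, and it did in Carya. TRINITY_DN15378_c0_g2_i8_1 stood at 860 ± 26.0 FPKM with T. panzhihuanense, 58.2 ± 2.05 with T. indicum and 249 ± 10.8 in controls (SD, n = 4 each), so the 2 inoculated groups lay on opposite sides of control; the log2 fold change between the truffles was 3.86 ± 0.05 (SE; adjusted p = 2.26e-13). TRINITY_DN14253_c0_g1_i2_2 stood at 18.2 ± 1.21 FPKM with T. panzhihuanense and 0.0374 ± 0.0164 with T. indicum, against 10.8 ± 0.855 in controls (log2 fold change 4.21, adjusted p = 3.93e-12). TRINITY_DN1820_c0_g1_i2_3 was lower with T. panzhihuanense, at 2.26 ± 0.221 FPKM against 42.1 ± 1.30 with T. indicum and 15.5 ± 0.907 in controls (log2 fold change -3.73, adjusted p = 2.09e-12). TRINITY_DN19385_c0_g1_i1_4 stood at 0.636 ± 0.106 FPKM with T. panzhihuanense against 20.98 ± 2.28 with T. indicum (log2 fold change -3.74, adjusted p = 1.71e-11). Of 17941 contigs called by limma (53.2%), 4320 were higher and 13621 lower with T. panzhihuanense than with T. indicum, of which 1509 and 3281 changed by at least 1 on the log2 scale. Higher calls made up 24.1% as deposited, 44.5% after quantile normalization and 50.7% after centring, with a median over all contigs of -0.29 as deposited. The share as deposited was 45.1% for IDs ending in 2 and 17.4% for those ending in 3. In 5626 contigs, T. indicum leaves stood above both other groups, which were not called apart; after centring this held for 2349 contigs and after quantile normalization for 2742.

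In Carya, many contigs were called in the same direction against control with both truffles. Both inoculated groups were above control in 5876 contigs and below it in 3055, 8931 together, while 2288 contigs were called in opposite directions. The higher share of these shared calls depended on the scaling: 65.8% as deposited, 51.1% after quantile normalization (4303 higher, 4110 lower) and 46.4% after centring (4013 higher, 4635 lower). Independent lists of the same lengths would share 4562 contigs in the same direction and 4306 in opposite directions. With the controls split so that each truffle had its own pair, 6709 to 6979 contigs were called in the same direction by both. Across contigs, which are not independent replicates, the log2 fold changes of both truffles correlated with r = 0.566 against at most 0.519 for simulated unchanged groups that shared the controls. Their covariance was 0.308 against 0.0233 in the simulations, and 0.282 to 0.290 with split controls. A difference of the control group alone would also raise the overlap and the covariance, and split controls share it. These values therefore cannot tell a common response to both truffles from controls that stood apart.

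The same question for T. indicum in Pinus gave fewer calls than in Carya. TRINITY_DN15599_c0_g3_i2_2 was listed at 0 in all 4 controls and stood between 119 and 129 FPKM in the T. indicum libraries (adjusted p = 1.32e-12). TRINITY_DN11879_c0_g1_i1_4 rose from 4.71 ± 0.320 to 382 ± 25.1 FPKM (SD, n = 4 each), by 6.07 ± 0.06 on the log2 scale (SE; adjusted p = 1.45e-14). TRINITY_DN6997_c0_g2_i1_4 went from between 147 and 216 FPKM in controls to 0.323 FPKM in T. indicum replicate 1, 1.05e-48 in replicate 3 and a listed 0 in replicates 2 and 4 (adjusted p = 3.97e-11). TRINITY_DN15144_c0_g2_i4_3 fell by 7.19, from 171 ± 13.8 to 0.180 ± 0.132 FPKM (adjusted p = 6.91e-13). limma called 9541 of 26599 contigs (35.9%), 5883 higher and 3658 lower with T. indicum, of which 1210 and 897 changed by at least 1 on the log2 scale. Higher calls made up 61.7% as deposited, 51.2% after quantile normalization and 47.7% after centring; the median over all contigs lay 0.07 above control. As deposited, 68.6% of calls were higher for IDs ending in 2 and 48.6% for those ending in 3.

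Pinus leaves with T. panzhihuanense differed from control leaves in part through the same contigs as with T. indicum. TRINITY_DN12426_c0_g1_i2_2 stood between 816 and 1011 FPKM in controls and was listed at 0 in all 4 T. panzhihuanense libraries (adjusted p = 1.45e-13). TRINITY_DN15144_c0_g2_i4_3, which also fell with T. indicum, fell by 6.99, from 171 ± 13.8 to 0.363 ± 0.216 FPKM (SD, n = 4 each; adjusted p = 7.34e-13). TRINITY_DN15599_c0_g3_i2_2, listed at 0 in controls, stood between 35.3 and 59.8 FPKM (adjusted p = 1.50e-11), and TRINITY_DN20747_c0_g1_i1_4, also listed at 0 in controls, between 29.9 and 38.8 FPKM (adjusted p = 1.51e-10). limma called 10560 contigs (39.7%), 5702 higher and 4858 lower, of which 1891 and 943 changed by at least 1 on the log2 scale. The share of higher calls was 54.0% as deposited, 52.9% after centring and 43.6% after quantile normalization. It also turned with the end of the ID, from 42.2% for number 2 to 71.0% for number 3. Libraries 3 and 4 of this group held 153 contigs at 1 FPKM or more that were under 0.1 FPKM in libraries 1 and 2.

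Between the truffles, Pinus leaves differed in contigs that were listed at 0 with only 1 of the fungi. TRINITY_DN4198_c0_g1_i1_4 was listed at 0 in all 4 T. indicum libraries and stood between 119 and 134 FPKM with T. panzhihuanense and between 83.5 and 139 FPKM in controls (adjusted p = 8.48e-13). TRINITY_DN17022_c1_g1_i1_3 was listed at 0 in all 4 T. panzhihuanense libraries and stood between 176 and 202 FPKM with T. indicum (adjusted p = 8.97e-15). TRINITY_DN12426_c0_g1_i2_2, listed at 0 with T. panzhihuanense, stood between 209 and 342 FPKM with T. indicum (adjusted p = 1.02e-12). TRINITY_DN6997_c0_g2_i1_4 stood between 62.4 and 127 FPKM with T. panzhihuanense, above the T. indicum values given before (adjusted p = 1.06e-10). limma called 11288 contigs (42.4%), 4568 higher and 6720 lower with T. panzhihuanense, while of those that changed by at least 1 on the log2 scale 1821 were higher and 1071 lower, the opposite balance. Higher calls made up 40.5% as deposited, 40.3% after quantile normalization and 52.3% after centring, which sets the median log2 ratio to about 0 by construction. The direction differed by ID ending, with 22.4% of calls higher for number 2 and 67.8% for number 3.

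Calls in the same direction against control with both truffles were also found in Pinus. Both inoculated groups were above control in 2409 contigs and below it in 1875, 4284 together, while 1159 were called in opposite directions. Of the shared calls, 56.2% were higher as deposited, 43.7% after quantile normalization (1939 higher, 2498 lower) and 46.5% after centring (2025 higher, 2332 lower), so the larger direction is not settled. Independent lists would share 1929 contigs in the same direction and 1859 in opposite directions. With split controls, 2814 to 2939 contigs were called in the same direction by both. The correlation across contigs was 0.422, no higher than in the simulated unchanged groups (at most 0.515), while the covariance was 0.178 against 0.0180 in the simulations and 0.151 to 0.167 with split controls. As in Carya, these values cannot tell a common response from controls that stood apart. Control stood above both other groups, not called apart, in 1132 contigs and below them in 1501. The same counts were 1941 and 1887 for T. panzhihuanense and 2159 and 822 for T. indicum. Because the contigs of both species come from separate tables and carry no gene names, changes were not matched between the hosts.

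**Figure D3:**
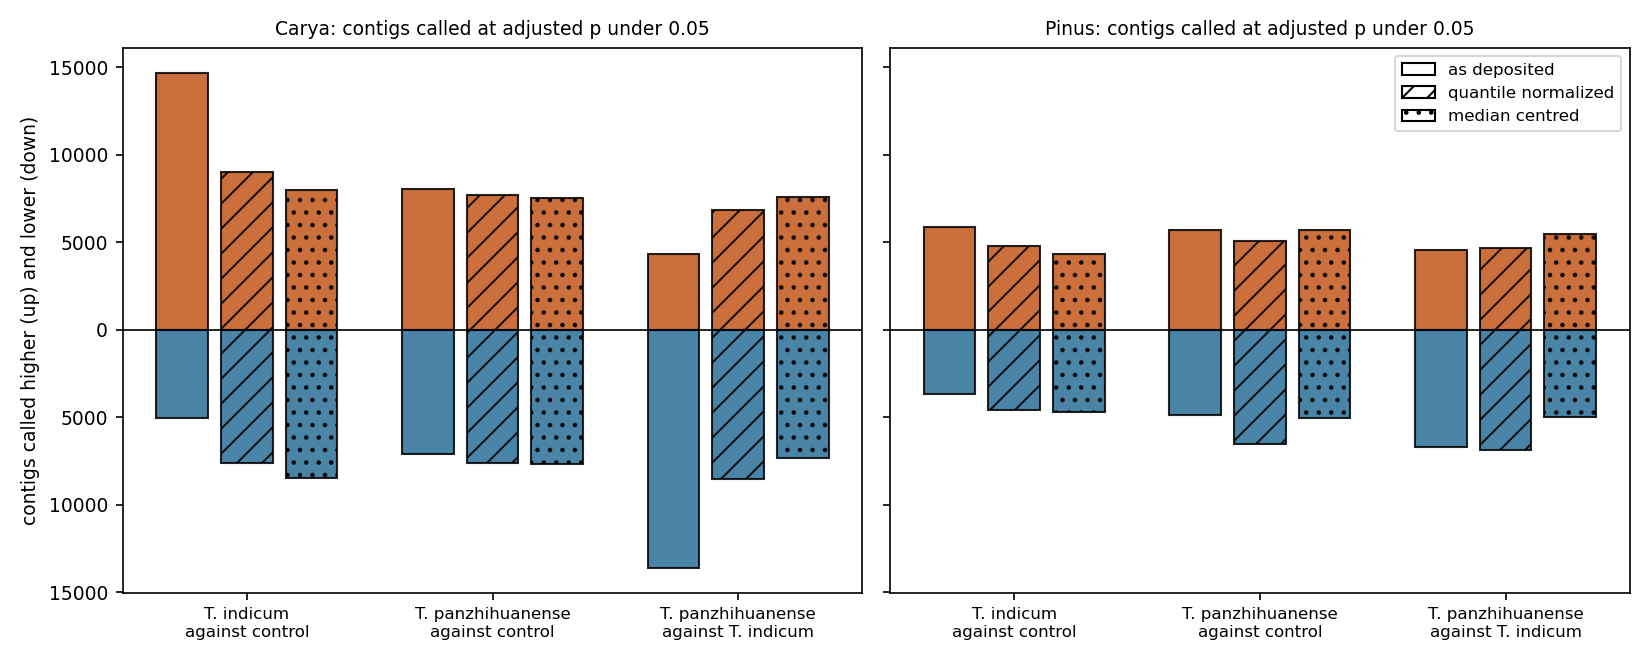
Number of contigs called higher (above 0) and lower (below 0) by limma in each comparison, for values as deposited (plain bars), after quantile normalization (hatched) and after median centring (dotted). For Carya T. indicum against control, 14688 contigs were higher and 5052 lower as deposited, and 7984 and 8503 after centring.

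**Figure D4:**
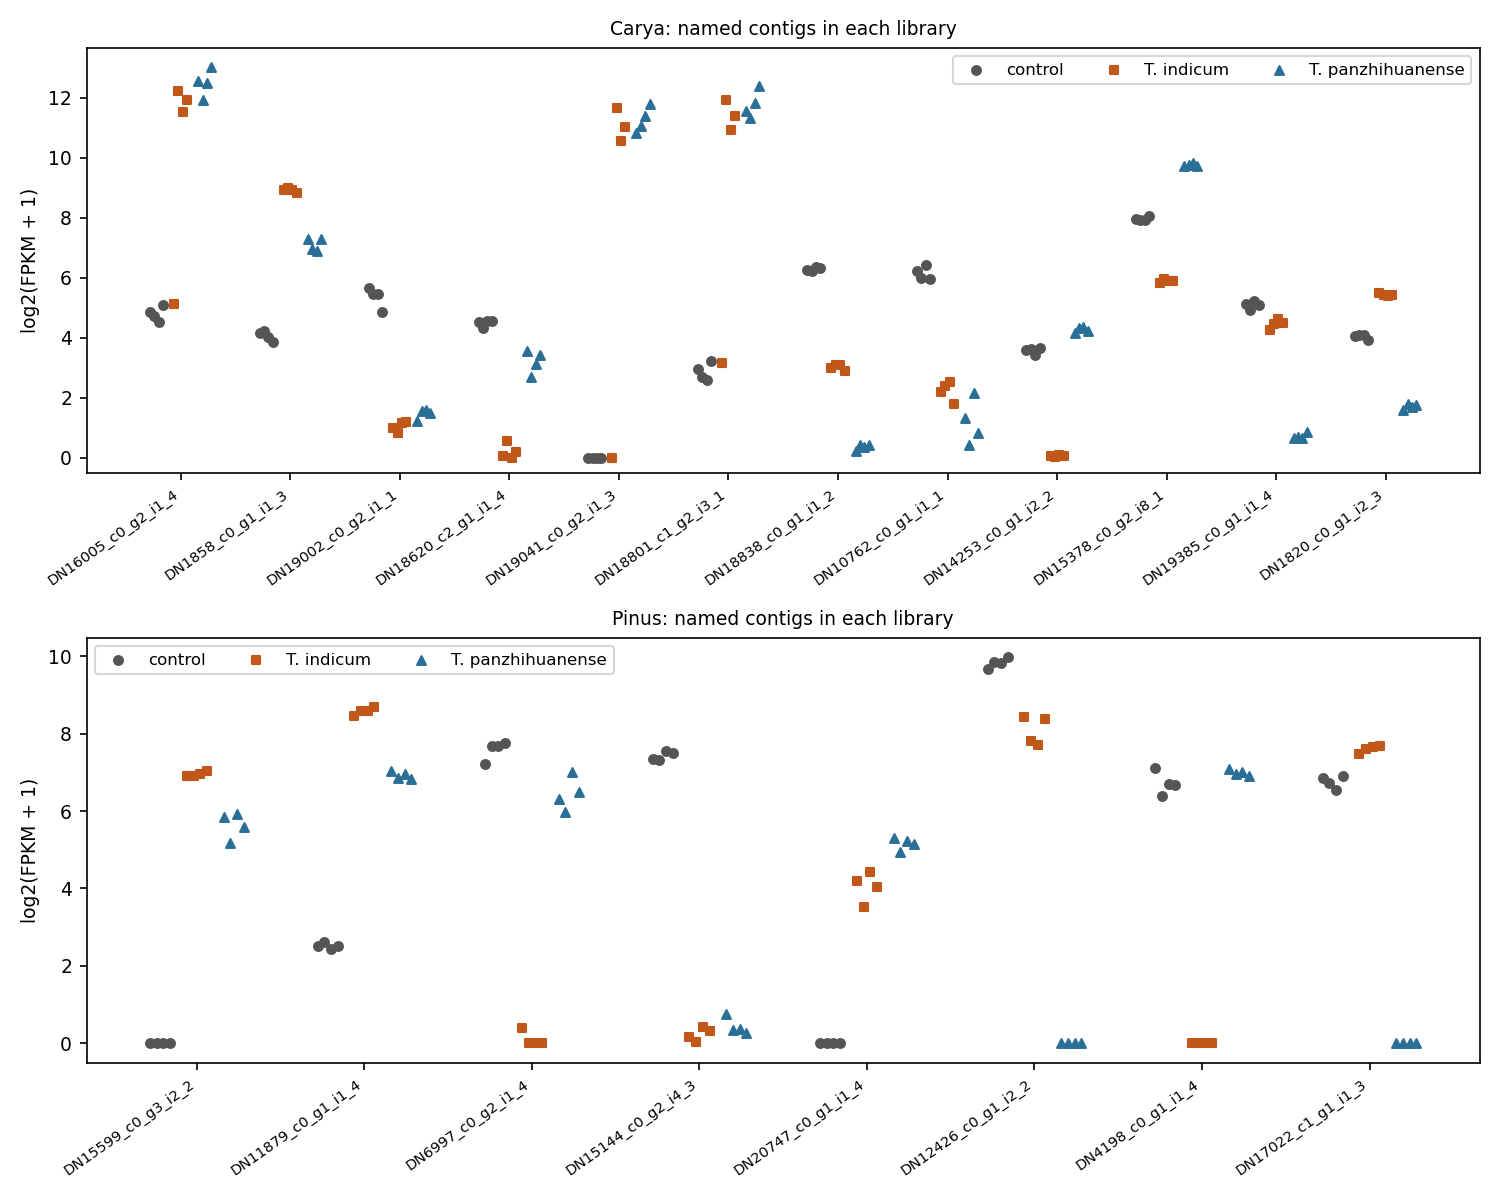
Values of the named contigs, log2(FPKM + 1), with 1 point per library and colour and shape giving the group, Carya above and Pinus below. In Carya, T. indicum replicate 1 lies with the controls for TRINITY_DN16005_c0_g2_i1_4, at 33.5 FPKM.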

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

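The tests of explanations and the comparisons of library measures between hosts in this part were chosen after the values had been seen; the counts over other splits of the libraries were planned. In each of the 6 comparisons, fitted on its 8 libraries alone, only the real grouping, 1 of 35 splits into 4 and 4, reached its number of called contigs. In Carya the real splits gave 20482, 14415 and 17041 contigs, for T. indicum against control, T. panzhihuanense against control and T. panzhihuanense against T. indicum, and the highest other split gave 0 each time. In Pinus the real splits gave 9334, 10881 and 10119, and the highest other split gave 0, 1 and 1. The other splits mix libraries of groups that differ, which adds that difference to the spread. Their counts are therefore low by construction and do not measure false calls.

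In 3 of 102 groups of 4, a single library stood far from the other 3, where chance gives about 5% of groups. TRINITY_DN1820_c0_g1_i2_3 stood at 14.1 FPKM in Carya control replicate 4 and between 15.8 and 16.0 in the other controls. The relative depth of Pinus T. panzhihuanense replicate 3 was 0.981, against 1.01 in each of the other 3. TRINITY_DN6997_c0_g2_i1_4 stood at 0.323 FPKM in Pinus T. indicum replicate 1 and at or near 0 in the other 3. On this scale a wide range among the remaining libraries hides an odd one, so the count does not cover all odd libraries. For TRINITY_DN16005_c0_g2_i1_4, Carya T. indicum replicate 1 stood at 33.5 FPKM and the rest of its group between 2937 and 4793, and it was not flagged. TRINITY_DN18801_c1_g2_i3_1 and TRINITY_DN19041_c0_g2_i1_3 were not flagged in that group either.

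The change in library profile with a truffle differed between the 2 hosts in 3 of 6 permutation tests. In these tests the values, centred within each species, were permuted between the species in all 4900 ways within treatments. The hosts have separate tables, and any other difference between the groups of a species, sequencing depth included, would enter these values. The tests therefore cannot tell a difference in host response from such differences. The log2 change of the median contig with T. indicum was 0.43 in Carya and 0.12 in Pinus, a difference of 0.31 (permutation p = 0.00531, adjusted p = 0.0159). For T. panzhihuanense, the log2 change of the effective number of contigs was -0.06 in Carya and 0.19 in Pinus, a difference of -0.25 (permutation p = 0.0139, adjusted p = 0.0278); without the contigs that switch together inside the T. indicum group it was -0.18 (adjusted p = 0.0849), so it rests in part on those contigs. The log2 change of the share of the 100 most abundant contigs with T. panzhihuanense was 0.21 in Carya and -0.16 in Pinus, a difference of 0.38 (permutation p = 0.000408, adjusted p = 0.00245), and of 0.29 without those contigs (permutation p = 0.000816, adjusted p = 0.00490).

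The rise of the median contig in Carya T. indicum leaves, with a more even profile, was weighed against 3 technical explanations. A single scale factor per library cannot change the effective number of contigs. That number was 1.28 times that of controls with no overlap, so a scale factor does not explain the pattern. Sequencing depth stays open. The mean relative depths of both groups had a ratio of 1.02, but the estimate could not find a large difference. Carya T. indicum libraries also listed fewer contigs at 0 than controls (956 against 1568 on average), which deeper libraries would also give. The number that ends each contig ID does not carry it alone either, since the median log2 fold change lay above 0 for all 4 numbers, the lowest being 0.13 (95% bootstrap interval over contigs 0.12 to 0.15) and the highest 0.54. Inoculation with T. indicum is a candidate explanation, and Pinus leaves with this truffle also had 1.20 times as many effective contigs as controls. Pinus leaves with T. panzhihuanense had 1.14 times as many, so the Pinus result was not particular to T. indicum. The Pinus median contig with T. indicum was 1.09 times that of controls (exact permutation p = 0.0571). Inoculation cannot be told apart from any other difference between the seedlings of a group, such as growth, leaf age or day of harvest. These last were not tested.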

How the results depend on the processing

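The Pinus fit without T. panzhihuanense libraries 3 and 4, the alternatives for library measures and gaps, and those for the overlaps other than the pseudocount and split controls were chosen after seeing the data. All 252 values of named Carya contigs and 264 of named Pinus contigs under alternatives kept their direction and an adjusted p under 0.05. The named contigs had been picked for the largest changes in the same data, so this does not carry over to other calls. The sizes of the named changes could move with a pseudocount of 0.1 where a group was near 0. Between the truffles, TRINITY_DN14253_c0_g1_i2_2 went from 4.21 to 7.06, while TRINITY_DN15378_c0_g2_i8_1 went only from 3.86 to 3.88. For T. indicum against control, TRINITY_DN18620_c2_g1_i1_4 went from -4.28 to -6.66. Among the counts, 173 stayed within 1.5 times the value reported and 11 did not, all from a stricter threshold or fewer controls. With an absolute log2 fold change of at least 1, Carya gave 6420 contigs for T. indicum against control, 4361 for T. panzhihuanense against control, 4790 between the truffles and an overlap of 2107. Pinus gave 2107, 2834, 2892 and an overlap of 799. With split controls, which leave 2 libraries per control group, the Pinus overlap was 2839, 2814 and 2844 when T. indicum was set against controls 3 and 4, 1 and 4, or 2 and 3. Scaling left the totals within 1.5 times, while the counts per direction and the share of higher calls moved, as given beside the comparisons and overlaps. Leaving out each library in turn gave 18341 to 20048, 13834 to 15380 and 16400 to 17875 contigs in Carya and 8334 to 10142, 9272 to 11503 and 9995 to 11582 in Pinus, in the same order, with overlaps of 8116 to 8853 and 3624 to 4683. Without T. panzhihuanense libraries 3 and 4, Pinus gave 9350, 7865 and 9050. The differences in median contig, effective number and share of the 100 most abundant contigs with an exact permutation p of 0.0286 kept their direction when a library was left out, with an exact permutation p of at most 0.0571, or 2 of 35 arrangements. The smaller changes of the Pinus median contig with T. indicum and of the Carya effective number with T. panzhihuanense kept their direction with an exact permutation p of up to 0.0857 and 0.771. Without the contigs that switch together inside the T. indicum group, the Carya effective number with T. panzhihuanense was 1.01 times that of controls, against 0.961 with them.

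The replicate numbers did not pair the libraries: deviations of same-numbered libraries correlated with a mean r of -0.016 in Carya and -0.021 in Pinus, and 3 of 12 and 2 of 12 libraries correlated best with their own number. With a replicate block the counts were 19296, 14605 and 17425 in Carya and 8718, 9759 and 10460 in Pinus. The tests of gene lists with a preset or an estimated correlation, a block, another pseudocount or a library left out were not run, since the contigs carry no descriptions. Absolute depth is unknown, so no floor can be given for a contig listed at 0.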

Other observations

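All tests in this part were chosen after the values had been seen. The contigs named here were also chosen after their values were seen. Some contigs split the libraries of a species by a gap of at least 2 on the log2 scale, 153 in Carya and 272 in Pinus. In Pinus, 75 of these stood higher with T. panzhihuanense than in both other groups, 42 higher in control, 30 lower in control, 28 higher with T. indicum, 23 lower with T. panzhihuanense and 19 lower with T. indicum. The corresponding counts in Carya were 22, 21, 26, 18, 12 and 25. The shift of the Carya T. indicum leaves was smallest among abundant contigs: the median log2 fold change was 0.07 in the most abundant of 10 equal classes and 0.42 in class 6 from below. FPKM values are scaled to the fragments of each library, which may hold the most abundant class near 0, so this contrast may in part be set by the scaling.

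The gaps ran between whole groups in 81.05% of these contigs in Carya and 79.8% in Pinus. Dropout of values that is unrelated to group would place gaps inside groups as readily as between them, so dropout of that kind does not explain the pattern. Dropout that follows a depth difference between groups would place gaps between groups. It was not told apart, since the depth estimate could not find a large difference. A single library stood against all others in 20 contigs in Carya and 42 in Pinus, and 9 and 13 contigs had other gaps inside a group, most of which set a single T. indicum library apart from its group. Gaps between whole groups may come from plant material shared inside a group, for example seedlings of a single parent or pooled leaves, or from the inoculation, or may depend on how contigs entered the table, and none of these was told apart: of the 28 Pinus contigs higher with T. indicum, 16 had the end number 2 and 0 had 3, of the 75 higher with T. panzhihuanense 36 had 3, and of the 18 Carya contigs higher with T. indicum 9 had 3 and 0 had 2. With gaps of at least 1.5 the share was 83.7% in Carya and 73.3% in Pinus, and with gaps of at least 3 it was 53.3% (8 of 15 contigs) and 79.4%.

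A few abundant contigs switched together inside the T. indicum group. In Carya these were 6 contigs, among them TRINITY_DN16005_c0_g2_i1_4, TRINITY_DN18801_c1_g2_i3_1 and TRINITY_DN19041_c0_g2_i1_3. They summed to between 6841 and 18273 FPKM in T. indicum replicates 2 to 4 and all T. panzhihuanense libraries. In the controls and T. indicum replicate 1 they summed to between 45.2 and 71.1 FPKM. In Pinus 7 contigs, among them TRINITY_DN18098_c0_g3_i1_1, summed to at least 10352 FPKM in T. indicum replicates 1 to 3 and at most 107 FPKM elsewhere. The odd library had 1.01 times the estimated relative depth of its group in Carya and 0.976 times in Pinus. Sequencing depth does not explain the switch, since the odd library was not short of other contigs. It listed 721 contigs at 0 in Carya, against 805 to 1400 in the rest of its group. In Pinus it listed 1476, against 1265 to 1926. A wrong label does not explain the switch either. The Spearman correlation of the odd library with its own group exceeded that with controls by 0.080 and 0.047 on average, with no overlap. A common source of these contigs, such as an organism living in some leaves, could be a candidate explanation, and it stays open: the mean correlation between them over the libraries that held them lay at percentile 91.7 of 10000 random sets in Carya, where as few as 2 contigs matched a member, and at 76.6 in Pinus over only 3 libraries.

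In Pinus, T. panzhihuanense libraries 3 and 4 held 153 contigs at 1 FPKM or more that stood under 0.1 FPKM in libraries 1 and 2, while the other pairs within groups gave 4 to 31 such contigs. Of the 153, 132 carried the end number 3, against 24.1% of all contigs. Their values summed to 378 FPKM in library 3, 969 in library 4 and 153 in T. indicum library 1, and to between 0.0387 and 43.2 in the remaining libraries. With under 0.5 FPKM as the limit for libraries 1 and 2 there were 255 such contigs, and with at least 2 FPKM in libraries 3 and 4 there were 63.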
